A study of Mus musculus with 2 samples.

How the data were processed

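Droplet 3' single-cell RNA sequencing measured bone marrow cells sorted as Lin- Kit+ from 1 wild-type and 1 GATA-1 knock-in library. Lin- Kit+ marks progenitors that lack mature lineage markers and carry the Kit receptor. The deposited values are raw UMI counts per gene and cell barcode, per the file headers, which name Cell Ranger 3.1.0. A UMI is a tag that marks 1 captured RNA molecule. The reads were aligned to mm10, per the submitters' processing notes. The labels name a v2 reagent kit, and the kit could not be checked against the counts. The first barcodes of both files look like those of the later v3 kit, but no list of barcodes was at hand to test this. No header or label states how the authors chose the barcodes, and the smallest barcode total in each file was 500 UMIs. Of the 31053 gene IDs in the files, 30934 were found in the GENCODE M21 annotation, which gave positions, gene types and transcript lengths.

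The design (filters, clustering, markers, lists, the rule for named genes and most alternatives) was fixed before the data were examined. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as supplied in scanpy. The automatic call marked 2.96% of wild-type cells. It marked 0.0692% of knock-in cells, under the set minimum of 0.5%, so the top 5% of knock-in scores were removed instead. This left 5468 wild-type and 5500 knock-in cells, with 63856981 and 43629184 UMIs.

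Both libraries were clustered together without batch correction, from 2000 variable genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1. The members of 10 of the gene lists, together with Gata1, Xist, Tsix, Y-linked, mitochondrial and ribosomal protein genes, were left out of the variable genes. The stem cell and lymphoid lists were not among the 10, though some of their members also stand in lists that were. Clusters took a class name from fixed marker lists, and each name means that the cells resembled that class by those markers. A cluster stayed unnamed where the top 10 genes held more markers of another class than of its own. In that check, early and late erythroid markers were counted as 1 lineage. This pooling was decided after the clusters were seen, because clusters 3, 5 and 16 would otherwise have stayed unnamed. These 3 clusters held 14.6%, 0.0366% and 5.45% of wild-type cells and 0.127%, 13.2% and 0.145% of knock-in cells.

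UMIs were summed per library and class, and a gene's level is given as CPM, its count scaled by that sum. Ratios are knock-in over wild type on the log2 scale. Shares have exact 95% binomial (Clopper-Pearson) intervals, sums have exact Poisson intervals, and ratios of CPM have exact conditional binomial intervals. All intervals cover counting error only. Background RNA was neither estimated nor removed. With 1 library per genotype there was no test across samples, and no difference has a replicate check. A library at 0 was put at a floor of 3 UMIs, and only the interval of its ratio is a bound. Classes needed 100 cells in each library, which left out the late erythroid class, and list members needed 50 UMIs over both libraries in the class.

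The 24 lists were globin, heme synthesis, red cell membrane, iron handling, erythroid transcription factors, genes lowered in GATA1-driven maturation, megakaryocyte and platelet, mast and basophil, eosinophil granule, granulocyte and monocyte, lymphoid, stem cell, S phase, G2 and M phase, p53 targets and cell-cycle inhibitors, apoptosis regulators, integrated stress and unfolded protein response, interferon response, immediate early, cytokine receptors, mitophagy and autophagy, MHC class II, ribosomal proteins and mitochondrially encoded genes. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only. Ribosomal protein, mitochondrial, Xist, Tsix and Y-linked genes were not drawn for the random lists. The ribosomal protein and mitochondrially encoded lists were thus set against other genes, and their most abundant members may lack a match. The lists the text leads with, and those whose members it names, were chosen after the medians were seen.

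Genes were named by a fixed rule. It took Gata1 and Gata2 in each class compared. It took the genes whose ratio interval lay farthest from no difference, with at least 100 UMIs in the higher library: 10 in each direction in early erythroid and megakaryocyte cells, and 3 in each direction in the other classes and over all cells. From each list described it took up to 4 members with the most UMIs, and members at least 2-fold apart with 100 UMIs in the higher library. The text gives part of the genes the rule took. Mitochondrial, ribosomal protein and sex-linked marker genes were left out of the ranking, as were clustering genes that lead a cluster of the class.

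The ratio and percentile calculations were tested on simulated counts for the 12092 genes with enough UMIs in the cells that passed the filters, with 200 genes changed by known folds. Intervals held the true ratio for 95.4% of unchanged and 95.7% of changed genes. The counts were drawn with counting error only, the error the intervals are built for. This checks the calculation and not the variation between cells or libraries. The interval left out no difference, on the right side, for 84.0% of genes changed 1.25-fold, 91.9% at 1.5-fold, 99.7% at 2-fold and 100% at 4-fold. These rates hold for sums over whole libraries, and the sums of single classes hold fewer UMIs. Of 200 random lists of 15 unchanged genes, 4% lay outside the central 95% of the random lists.

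Alternatives were other cell filters, doublets kept, listed genes allowed in clustering, Leiden resolutions 0.6 and 1.6, knock-in cells placed on wild-type clusters, other scalings, clusters of a class weighted by wild-type shares, other UMI minimums and cells thinned to 2000 UMIs. After the data were seen, 4 more were added: knock-in early erythroid cells matched to wild-type clusters that were then weighted by their wild-type shares, a cluster with low Xist left out, early and late erythroid markers counted apart, and the shortest 10% of genes by transcript length left out. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.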

Results

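Sorted Lin- Kit+ bone marrow cells of 1 wild-type mouse library and 1 library with a knock-in mutation of GATA-1 were profiled cell by cell. GATA-1 is a transcription factor of the red cell, megakaryocyte, mast cell and eosinophil lineages. The stated purpose was to compare cell populations and gene regulation between the genotypes. The files held 7471 wild-type and 6640 knock-in barcodes with 70543211 and 48005467 UMIs. After filtering, 5468 and 5500 cells remained, with a median of 9610 and 5272.5 UMIs and 2738 and 1950 genes per cell. There were no replicates, so every difference below is between these 2 libraries.

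The level of Gata1 was similar between the genotypes in the 3 classes with the most Gata1 of those compared. In early erythroid cells Gata1 (ENSMUSG00000031162, chromosome X, 7959260 to 7978071, minus strand, mm10) stood at 149 CPM in wild type and 140 CPM in the knock-in, a log2 ratio of -0.09 (-0.15 to -0.03). It stood at 62.0 and 61.6 CPM in megakaryocyte cells and at 71.0 and 70.0 CPM in basophil and mast cells. Monocyte progenitors held little, and less in the knock-in (3.94 and 1.74 CPM, from 55 and 8 UMIs). Car1, an early erythroid marker, was lower there too (127 and 23.9 CPM), and in stem and multipotent, lymphoid-primed and megakaryocyte cells. It was higher in neutrophil progenitors (45.3 and 69.4 CPM) and in basophil and mast cells (55.3 and 74.9 CPM). Background RNA was not estimated. Over all cells Gata1 stood at 88.1 and 101 CPM. A knock-in mutation need not alter the level of its own transcript, so this does not check the genotype labels. Xist was detected in both libraries, at 901 and 1242 CPM over all cells, and the 4 Y-linked genes examined gave at most 1 UMI each.

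The knock-in library held more early erythroid cells and fewer myeloid progenitors. Early erythroid cells made up 40.1% (38.8 to 41.4) of wild-type and 56.4% (55.1 to 57.7) of knock-in cells, and 19.9% and 42.9% when early and late erythroid markers were counted apart in naming. Monocyte progenitors made up 21.1% (20.05 to 22.2) and 8.20% (7.49 to 8.96), and neutrophil progenitors 7.22% (6.55 to 7.94) and 2.13% (1.76 to 2.54), or 6.34% and 1.21% under the stricter cell filter. Megakaryocyte cells made up 4.39% (3.86 to 4.97) and 5.84% (5.23 to 6.49), or 240 and 321 cells. Cluster 12, unnamed though led by the megakaryocyte markers Pf4 and Cavin2, held 259 wild-type and 156 knock-in cells. Counting it with the megakaryocyte cells would turn their direction. At Leiden resolution 1.6, which left 0.293% and 0.909% of cells unnamed, megakaryocyte cells made up 7.53% and 9.38%. Stem and multipotent cells (14.8% and 15.9%), lymphoid-primed cells (4.17% and 4.25%) and basophil and mast cells (3.16% and 3.25%) had ratios whose counting intervals included no difference. Late erythroid cells numbered 1 and 17, but 42 and 18 under the stricter cell filter and 569 and 21 with doublets kept. Unnamed clusters held 5.03% and 3.75%. Among cells outside the erythroid classes, monocyte progenitors made up 35.3% (33.6 to 36.9) of wild-type and 18.9% (17.4 to 20.6) of knock-in cells, and stem and multipotent cells 24.7% (23.3 to 26.2) and 36.7% (34.8 to 38.7). The sort, the share of barcodes over the mitochondrial limit (23.0% and 11.4%) and the different depths can each set such shares. The direction for stem and multipotent cells turned under the stricter cell filter (log2 ratio -0.44) and under Leiden resolution 0.6 (-0.73), against 0.10 in the main analysis, and with knock-in cells placed on wild-type clusters the shares were 13.4% and 13.3%.

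**Figure D1:**
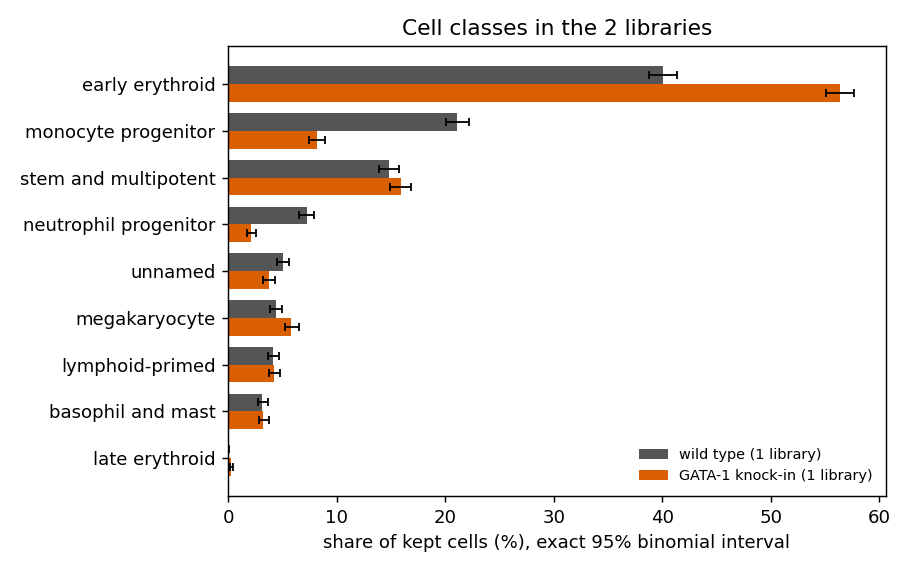
Share of kept cells (%) in each cell class for the wild-type and the knock-in library, with exact 95% binomial intervals for counting error. Early erythroid cells stood at 40.1% and 56.4%, and monocyte progenitors at 21.1% and 8.20%.

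Within the early erythroid class the libraries hardly mixed. Wild-type cells lay in clusters 3, 7, 13 and 16, which held 36.6%, 25.7%, 17.2% and 13.6% of the wild-type cells of the class. Knock-in cells lay in clusters 1, 5, 6 and 11, with 37.5%, 23.4%, 21.7% and 13.4% of the knock-in cells. Cluster 17 held 4.06% and 2.06%. On average 94.5% of the 15 nearest neighbours of an early erythroid cell came from its own library, against 71.8% to 76.2% in the other 6 classes compared. With 117 cells per library drawn from each class, the early erythroid share was 79.2% and the highest other share 74.2%.

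**Figure D2:**
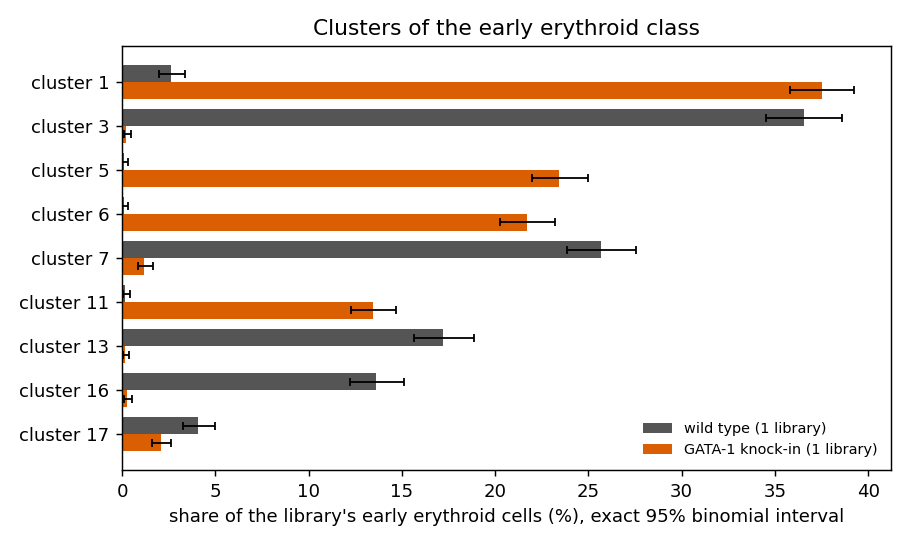
Share of each library's early erythroid cells (%) in each cluster of the class, with exact 95% binomial intervals. Cluster 1 held 2.60% of wild-type and 37.5% of knock-in cells, and cluster 3 held 36.6% and 0.226%.

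Genes that GATA-1 lowers as red cell precursors mature were higher in knock-in early erythroid cells, and heme synthesis genes were lower. Of the 13 genes lowered in GATA1-driven maturation, 12 were higher, with a median log2 ratio of 0.69 (percentile 100). Gata2, the GATA factor of earlier progenitors that GATA-1 replaces, stood at 58.9 CPM in wild type and 134 CPM in the knock-in (log2 ratio 1.19, 1.11 to 1.27). Myb, a factor of immature progenitors, stood at 355 and 570 CPM, and Meis1, a stem cell factor, was higher by 1.09 (0.91 to 1.26). Kit was close to level (135.7 and 137.1 CPM). Of 12 heme synthesis genes, 10 were lower, with a median of -0.24 (percentile 0.04). Ppox, which makes protoporphyrin, stood at 39.9 and 16.8 CPM (log2 ratio -1.24, -1.40 to -1.09), but it was lower in all 4 classes measured (-1.24 to -0.55). Cpox, the enzyme before it, stood at 283 and 216 CPM. The clusters that held these cells differed between the libraries, and with knock-in cells matched to wild-type clusters the medians were 0.25 and -0.13. Both medians turned sign, to -0.023 and 0.17, when early and late erythroid markers were counted apart in naming. This leaves clusters 3, 5 and 16 out of the class, and keeps 1090 of 2191 wild-type and 2359 of 3101 knock-in cells. The clusters left out had the most Cpox of the class (324, 283 and 360 CPM). Cluster 11, nearly all knock-in cells and with 248 CPM, stayed. The turns of sign can thus follow from which cells were left out. With the markers counted apart Gata2 stood at a log2 ratio of 0.099, Meis1 at -0.023 and Cpox at 0.48. With clusters matched Gata2 stood at 0.57 and Meis1 at 0.25.

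Other red cell genes showed no common direction. The erythroid transcription factor list had a median of 0.13 (percentile 94.4), with 9 of 15 members higher. Klf1, a main activator of red cell genes, stood at 279 and 304 CPM, and Zfpm1, the GATA-1 cofactor FOG1, was higher by 0.40 (0.35 to 0.46). Red cell membrane genes had a median of -0.03 (percentile 15.4). Within that list Rhag stood at 84.3 and 44.5 CPM and Rhd at 196 and 125 CPM, whereas Ermap was higher by 0.17 (0.13 to 0.21). With early and late erythroid markers counted apart, the log2 ratios were -0.04 for Rhag, 0.29 for Rhd and 0.76 for Ermap. Iron handling genes had a median of -0.05 (percentile 22.3).

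Mast and basophil genes and most p53 targets and cell-cycle inhibitors were higher in knock-in early erythroid cells. All 6 measured mast and basophil genes were higher, with a median of 1.14 (percentile 100). Ms4a2, a chain of the IgE receptor, stood at 0.943 and 7.26 CPM, and Cpa3, a mast cell protease, at 4.83 and 10.9 CPM, both far below the levels in basophil and mast cells. With early and late erythroid markers counted apart, Ms4a2 stood at a log2 ratio of 2.02 and Cpa3 at 0.087, and with clusters matched at 1.83 and 0.53. Of 13 p53 targets and cell-cycle inhibitors, 10 were higher, with a median of 0.47 (percentile 99.9). Cdkn1a, the inhibitor p21, stood at 0.884 and 3.74 CPM and Phlda3 at 7.72 and 16.4 CPM. Of the same list, Btg2 was higher in the main analysis but stood at a log2 ratio of -0.069 with clusters matched. With early and late erythroid markers counted apart Btg2 stood at -0.56 and Cdkn1b, also higher in the main analysis, at -0.042. Bax, lower in the main analysis, then stood at 0.13. Cdkn1a was higher in all 6 classes measured (log2 ratio 1.22 to 2.08), so this was not particular to early erythroid cells. The apoptosis list had a median of 0.05 (percentile 59.1).

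RNA of granulocyte and monocyte genes and of interferon response genes was lower in knock-in early erythroid cells. The granulocyte and monocyte list had a median of -1.02 (percentile 0), with 9 of 12 members lower. Mpo and Elane, enzymes of neutrophil granules, stood at 128 and 41.2 CPM and at 89.5 and 28.9 CPM. The same genes were lower in the knock-in in megakaryocyte cells (Elane 215 and 47.3 CPM), beside a lower share of the myeloid progenitors that make them. Background RNA was not estimated, so this RNA need not come from the erythroid or megakaryocyte cells. Of 15 interferon response genes 13 were lower, with a median of -0.42 (percentile 0), or -1.07 when early and late erythroid markers were counted apart, among them Bst2 at 100.4 and 41.1 CPM.

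Globin genes were higher in knock-in early erythroid cells, with a median of 1.92 over 4 genes (percentile 100), but 0.29 with listed genes allowed in clustering. Hba-a1, an alpha-globin gene, had 915 wild-type and 1947 knock-in UMIs, and 2 knock-in cells held 951 of the 1947. Hbb-bs, a beta-globin gene, stood at 11.4 and 76.0 CPM, but 2 knock-in cells held 1819 of its 2219 UMIs. Hbb-bs also stood at 2.93 and 27.2 CPM in stem and multipotent cells. It was higher in the knock-in in each of the 7 classes compared (log2 ratio 2.39 to 4.23), on few UMIs in some. Background RNA was not estimated, so this RNA need not come from the cells of each class. At least 1 Hbb-bs UMI was found in 11.9% of knock-in early erythroid cells and in 11.6% of knock-in stem and multipotent cells, at median depths of 6132 and 3925 UMIs. In wild type the shares were 5.80% and 1.98%, at 15281 and 5811.5 UMIs.

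The remaining lists in early erythroid cells had these medians. The G2 and M phase list stood at -0.27, with 0 of 23 members higher (percentile 0), and the S phase list at -0.17 (percentile 0.02). The stem cell list stood at 0.57 (percentile 99.99), the megakaryocyte and platelet list at 0.53 (percentile 95.9), the lymphoid list at 0.71 (percentile 95.3) and the MHC class II list at 0.75 (percentile 99.2). Cytokine receptors stood at 0.46 (percentile 99.5), immediate early genes at 0.20 (percentile 98.6), mitophagy and autophagy genes at 0.17 (percentile 93.3) and the integrated stress and unfolded protein response list at 0.04 (percentile 62.4). Ribosomal proteins stood at 0.13 (percentile 100) and mitochondrially encoded genes at -0.06 (percentile 24.3), both against random lists that held no genes of either kind. With clusters matched, the stem cell median was 0.11, the megakaryocyte and platelet median -0.05 and the immediate early median -0.22. The G2 and M phase median was 0.39 with doublets kept and 1.47 with early and late erythroid markers counted apart, and in the second setting the medians were -0.0063 for MHC class II, -0.15 for megakaryocyte and platelet, -0.12 for lymphoid and -0.64 for immediate early genes. That setting kept cluster 11, nearly all knock-in cells and with the most Mki67 of the class (579 CPM). It left out cluster 3, nearly all wild-type cells and next by Mki67 (401 CPM).

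**Figure D3:**
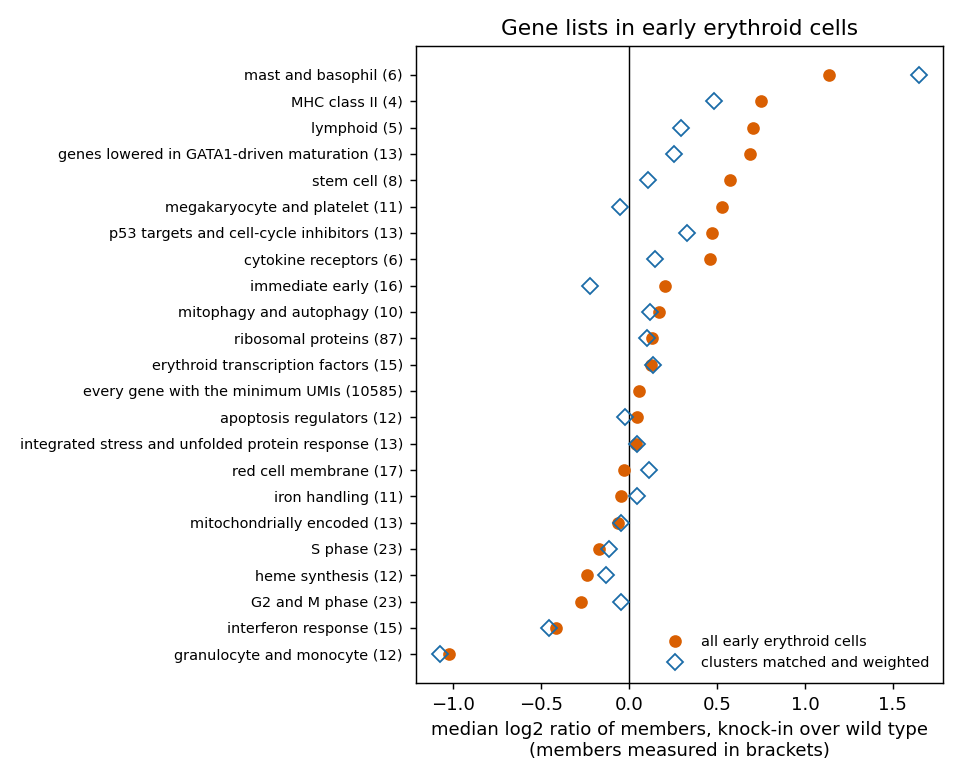
Median log2 ratio (knock-in over wild type) of each gene list in early erythroid cells, for all cells of the class and for knock-in cells matched to wild-type clusters, with the number of measured members in brackets. The mast and basophil list stood at 1.14 and 1.65, and the heme synthesis list at -0.24 and -0.13. The globin list (1.92 and 5.42) is not drawn.

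Among single genes in early erythroid cells, Ccnb1ip1 (ENSMUSG00000071470, chromosome 14, 50789248 to 50807732) had 44 wild-type and 1053 knock-in UMIs. Trnp1 had 1 and 268 UMIs, and Inpp4b, which was higher in all 4 classes measured, had 15 and 380. In the other direction, the non-coding gene Gm42047 had 954 and 0 UMIs and Pnp2 had 625 and 0, with log2 ratio intervals that end at -7.79 and -7.18. Acsl6 had 274 and 15 UMIs. Over all cells, Gm42047 (1686 and 0 UMIs) and Pnp2 (749 and 0) were again among the genes farthest apart. Ifi202b, also among them, had 0 and 175 UMIs, of which 138 lay in knock-in monocyte progenitors. Slc4a1, the red cell anion exchanger, had 2 and 145 UMIs, the 145 from 20 knock-in cells. Apoe, which encodes a lipid carrier, was lower in the knock-in outside the erythroid lineage too, at 302 and 15.5 CPM in stem and multipotent cells. Pnp2 and Ifi202b have close relatives in the genome, so their counts are uncertain. Pnp2 (chromosome 14, 50955992 to 50964749) lies within 1 Mb of Ccnb1ip1. Gm26782, lower in all 4 classes measured, lies between them. Ifi202b lies within 1 Mb of Ifi203 and Mndal on chromosome 1, both higher in all 7 classes. Whether such neighbours share a cause was not tested for these genes.

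Platelet genes of megakaryocyte cells moved both ways. Of the 12 measured members of the megakaryocyte and platelet list, 6 were higher and 6 lower, with a median of -0.02 (percentile 16.7), and the list summed to 4121 and 3310 CPM. Pf4, a platelet chemokine, stood at a log2 ratio of -0.52 (-0.58 to -0.45), and Cavin2 was higher by 0.67 (0.44 to 0.91). All 13 measured immediate early genes were lower, with a median of -0.71 (percentile 0), among them Fos at 634 and 265 CPM and Klf6 at 226 and 92.7 CPM. The immediate early median was -0.41 under the looser cell filter. Of this list Klf2, Zfp36 and Dusp1 were lower in all 7 classes, though in early erythroid cells the list median was higher in the knock-in in the main analysis. With clusters matched, or with early and late erythroid markers counted apart, the early erythroid median was lower too. The S phase list stood at 0.25 (percentile 99.91) and Gata2 at 236 and 266 CPM. Among the 10 genes highest by the rule, Slamf1, a surface marker of stem cells and megakaryocyte progenitors, stood at 23.0 and 80.3 CPM.

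Basophil and mast cells held less of the basophil proteases in the knock-in. Prss34 stood at 1100 and 132 CPM and Mcpt8 at 358 and 82.1 CPM, but 3 wild-type cells held 716 of 1193 Prss34 UMIs and 197 of 388 Mcpt8 UMIs. By contrast Cpa3 (841 and 743 CPM) and Ms4a2 (318 and 326 CPM), of the same mast and basophil list, were close. The mast and basophil list had a median of 0.04 (percentile 60.2), and Csf2rb, the shared chain of cytokine receptors, stood at 66.4 and 187 CPM. The eosinophil granule list, of 3 genes, stood at -3.32 (percentile 0), which rests on few cells. Of 1361 wild-type Prg2 UMIs, 1359 lay in 3 cells, as did 141 of 144 Prg3 UMIs, and over the alternatives that moved it most the median went from -6.60 (knock-in cells placed on wild-type clusters) to -0.81 (members with 1 or more UMIs counted). Gata2 stood at 431 and 477 CPM.

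Granule genes of monocyte and neutrophil progenitors moved both ways. The granulocyte and monocyte list had a median of -0.03 in monocyte progenitors (percentile 20.9) and 0.02 in neutrophil progenitors (percentile 42.7, 7 members higher and 7 lower). Elane was lower in both, at log2 ratios of -0.28 (-0.30 to -0.26) and -0.27 (-0.30 to -0.24), as was Prtn3, another granule protease (-0.18 and -0.26). In monocyte progenitors Mpo stood at 6429 and 6298 CPM, and Ctsg was higher by 0.29 (0.26 to 0.32). Immediate early genes were lower there, with 15 of 16 members lower and a median of -0.58 (percentile 0). In neutrophil progenitors the G2 and M phase list stood at -0.66 (percentile 0), with 19 of 21 members lower. Ngp and Camp, late granule genes, had 215 and 233 UMIs in the knock-in, all from 2 cells.

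Stem and multipotent cells and lymphoid-primed cells had similar Gata2 levels in both genotypes, at 88.2 and 92.2 CPM in the first and 23.1 and 21.2 CPM in the second. The stem cell list was higher in stem and multipotent cells, with a median of 0.23 (percentile 99.8), among them Ifitm1 at 546 and 842 CPM. Their G2 and M phase list stood at -0.35 (percentile 0), but at 0.056 when clusters were weighted by wild-type shares. In lymphoid-primed cells the lymphoid list had a median of 0.13 (percentile 86.6), with Dntt, the enzyme that adds nucleotides to rearranging receptor genes, at 630 and 740 CPM. The stem cell and lymphoid lists were not left out of clustering as lists. Members of both, among them Ifitm1 and Dntt, were also markers that named these classes. Their medians are thus not independent of how the classes were built. In lymphoid-primed cells all 10 measured interferon response genes were lower, with a median of -0.68 (percentile 0), among them Bst2 at 171 and 41.3 CPM.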

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

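The 4 alternatives added after the data were seen are matched clusters, the low-Xist cluster left out, erythroid markers counted apart and short genes left out. Across 77 alternative values of 8 class shares, 59 stayed inside the counting interval of the main value, 16 moved out of it and 2 turned sign from an interval that excluded 0. Of 2538 alternative list medians, 2455, 70 and 13 did so, and of 2142 alternative ratios of 178 named genes, 1826, 294 and 22. Counting every sign, also of values near 0, 11 shares, 218 list medians and 60 gene ratios had the other sign than the main value. The causes were not tested. Monocyte progenitors (log2 share ratio -1.65 to -1.30), neutrophil progenitors (-2.39 to -1.37), early erythroid cells (0.40 to 1.11) and megakaryocyte cells (0.26 to 0.94) kept their direction under every alternative run. Counting the unnamed cluster 12 with the megakaryocyte cells, which would turn their direction, was not among the alternatives. The other scalings moved the median of all genes by at most 0.0975.

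With the looser cell filter the share ratios were 0.29 for stem and multipotent, -1.37 for neutrophil progenitor, 0.94 for megakaryocyte and 0.68 for early erythroid cells, and Cxcl10 in neutrophil progenitors stood at 0.90. With the stricter filter they were -0.44 for stem and multipotent, -2.39 for neutrophil progenitor and -1.22 for late erythroid cells, the globin median was 3.59, and in stem and multipotent cells the S phase and the G2 and M phase medians were 0.018 and 0.044. With doublets kept, early erythroid cells stood at 0.86 and late erythroid cells at -4.80, Gata1 in early erythroid cells at 0.0085, Birc5 at 0.062 and Mcl1 at -0.014. The G2 and M phase medians were then 0.39 in early erythroid and -0.12 in basophil and mast cells, and the MHC class II median in megakaryocyte cells was 0.12.

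At Leiden resolution 0.6 stem and multipotent cells stood at -0.73 and their G2 and M phase median at 0.13. At resolution 1.6 early erythroid cells stood at 0.42 and the MHC class II median in megakaryocyte cells at 0.14. With clusters weighted by wild-type shares the G2 and M phase median in stem and multipotent cells was 0.056. With listed genes allowed, monocyte progenitors stood at -1.65, the globin median at 0.29 and Mpo in monocyte progenitors at 0.043. With knock-in cells placed on wild-type clusters, neutrophil progenitors stood at -2.11, basophil and mast cells at -0.39, the globin median at 4.98, the MHC class II median in megakaryocyte cells at 0.090, Mpo in monocyte progenitors at 0.055 and Cd52 in lymphoid-primed cells at 0.027. Thinned to 2000 UMIs, which left out 107 wild-type and 299 knock-in cells, the share ratios were -2.25 for neutrophil progenitors, 0.68 for megakaryocyte and 0.40 for early erythroid cells. With median-ratio size factors Mpo in neutrophil progenitors stood at -0.045.

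In early erythroid cells with clusters matched, the globin median was 5.42 and the heme synthesis median -0.13, Gata1 stood at -0.0238, Btg2 at -0.0691, Mcl1 at -0.10 and Myc at -0.0173. With early and late erythroid markers counted apart, early erythroid cells stood at 1.11, and the medians were 0.17 for heme synthesis, 0.28 for red cell membrane, -0.023 for genes lowered in GATA1-driven maturation, 1.47 for G2 and M phase and -0.0063 for MHC class II. In that setting Gata1 stood at -0.021, Alad at 0.20, Bax at 0.13, Birc5 at 1.47, Btg2 at -0.56, Cdkn1b at -0.0419, Cpox at 0.48, Mcl1 at -0.24, Meis1 at -0.023, Myc at -0.14, Rhd at 0.29 and Srgn at -0.099. The clusters it leaves out had the most Cpox of the class and held a larger part of the wild-type cells. Such changes can thus follow from which cells were left out.

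Weighting by wild-type shares was run only for stem and multipotent cells and monocyte progenitors. In early erythroid cells most clusters held too few cells of 1 library, and the other classes were single clusters. Values that an alternative could not give, such as lists with too few members, were left out. Depth limits list members with few UMIs, and with 1 library per genotype no alternative stands in for a replicate.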

Other observations

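The tests of depth and number of cells, of transcript length in the lower and in all genes and of neighbouring positions were chosen after the results they address had been seen, and the matched clusters were added after the data were examined. The bound on short transcripts over all genes was set after its values had been seen, and the 2 tests without genes that differ in the other classes were set to decide nothing after their values were seen. The median log2 ratio of the interferon response list was below 0 in each of the 7 classes compared, though few single members were clear of 0 in some: 4 of 14 in stem and multipotent, 4 of 10 in monocyte progenitor, 2 of 6 in neutrophil progenitor and 2 of 5 in basophil and mast cells had an interval below 0. The median was -0.42 in early erythroid, -0.28 in stem and multipotent, -0.68 in lymphoid-primed, -0.39 in neutrophil progenitor, -0.29 in monocyte progenitor, -0.51 in megakaryocyte and -0.43 in basophil and mast cells. The median of the ribosomal protein list was higher in all 7, from 0.10 to 0.15, but its members moved both ways and their summed CPM was lower in 6 of the 7. A small unnamed cluster, number 19, led by Cd74, Igkc and Cd79a, held 1 wild-type and 32 knock-in cells.

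Early erythroid cells of the libraries lay apart, with 94.5% of neighbours from the same library. Differences that every class carries stay open as a cause. Without genes 1.5-fold apart in the other classes the share was 85.8%, against at most 66.7% in another class, but the early erythroid class is the largest. Drawn to 117 cells per library, the shares were 79.2% and 74.2% with all genes, and 69.2% and 66.8% without those genes, so neither form decides. Depth and number of cells stay open too. With the same number of cells per library and 2000 UMIs per cell the share was 72.4%, against 67.2% in the highest other class, a gap which lies between the bounds of 5 and 10 points. The genotype is a biological explanation that stays open and untested, since it cannot be separated from the library.

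The higher genes lowered in GATA1-driven maturation and the lower heme synthesis genes in early erythroid cells may reflect more immature cells in the knock-in class. With knock-in cells matched to wild-type clusters, 36.9% of the first median (0.25) and 55.7% of the second (-0.13) was left. Both lie between the set bounds, so a mix of stages and a difference at the same stage cannot be told apart. Matching on neighbours also rests on cells that hardly mixed. A difference by genotype stays open for both lists.

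Many genes were lower in the knock-in in every class, and short transcripts recovered less in 1 library and linked strain variants were weighed as explanations. Of the 100 genes with the lowest median ratio, 28 lay in the shortest 10% by transcript length, against 7 to 19 in the central 95% of random sets, and 39 had another of the 100 within 1 Mb, against 8 to 27. Both counts go with the explanations, but the second cannot tell linked variants from gene families that lie together. Hist1, H2-Q and Ccl genes were among the 39, and the random sets were matched on UMIs only. Over all genes the median of the shortest 10% lay from 0.095 below to 0.026 above the median of its class. Each of the 100 genes had a median of -0.808 or lower, the bound set for a loss common to all short transcripts. No class came near that bound, so no common loss as large as these drops was seen. The 100 were picked as the lowest genes, though, so a whole 10% could hardly reach their level. The longest 10% lay above the median of its class in each class, from 0.028 in megakaryocyte to 0.134 in basophil and mast cells. A smaller loss common to short transcripts, or a loss of some of them, stays open. For the 100 highest genes the numbers were 8 (random sets 4 to 15) and 20 (6 to 26), which decides neither. The sets were taken by median, so 91 of the lowest and 82 of the highest genes had 1 sign in all classes measured. A second form of these tests, kept to genes with 1 sign and without mitochondrial and sex-linked genes, was run first and was replaced by the form written down once its outcome had been seen. It gave 26 and 39 for the lower genes and 8 and 18 for the higher.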
